A study of Mus musculus with 12 samples.

How the data were processed

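Messenger RNA was measured in 12 YUMM1.7 melanoma tumors grown in immunodeficient mice. YUMM1.7 is a mouse melanoma line with an activated Braf allele that lacks Cdkn2a. The labels divide the tumors by PD-L2 overexpression (absent in the control tumors) and by treatment with vehicle or a BRAF inhibitor (BRAFi), which gives 4 groups of 3 tumors. The sample labels place the tumors in NSG mice and the series design places them in NOD/SCID mice, so the host strain is not settled here. The labels name separate tumors within each group. Per the labels, RNA was purified with an RNeasy micro kit and libraries were made with an unstranded TruSeq version 2 kit after poly(A) selection. The labels' protocol gives paired-end reads and the series design gives single-end reads of 50 bp from a HiSeq instrument, and this conflict could not be resolved from the values.

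The values used are FPKM (fragments per kilobase of transcript, scaled to each library's mapped total), which the authors deposited as a single table of 23940 genes in all 12 libraries. Per the submitters' processing notes, the build was mm9 and the tools were TopHat, TopHat2, Cuffnorm and Cuffdiff. Their versions, their roles, the annotation and the normalization settings are not given in the sources used here. Of the 23940 genes, 4192 were listed at 0 in every library. An exact 0 from this kind of estimate can be a failed fit, so genes at 0 are called "listed at 0" and no fold is given for them; the model estimates of 2 flagged genes are given with that limit. The libraries are unstranded, so reads of overlapping or antisense genes cannot be told apart, and values of near-identical copies (the hemoglobin genes, the prolactin family members Prl2c3 and Prl8a9, the mast cell protease Mcpt1 and the ribosomal protein family) are uncertain.

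The depth of each library is unknown. FPKM values of 5888 low genes were compared between the 66 pairs of libraries to look for steps of whole reads; the share of genes at a single ratio (within 0.1 on the log2 scale) was 0.04 to 0.29, too low to recover read numbers. No counting interval or detection floor is therefore given, and errors are spreads between tumors (SD) or standard errors of the fitted model (SE).

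Expression was analysed as log2(FPKM + 1) for the 12117 genes with a mean of at least 1 FPKM over the 12 libraries. Fold changes are on this scale and understate the change of genes with low FPKM. A linear model with a mean for each of the 4 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), so that the groups share 1 estimate of the spread. Every adjusted p of a gene is from limma's two-sided moderated test with Benjamini-Hochberg adjustment over the 12117 genes, and the threshold was 0.05. The comparisons were BRAFi against vehicle in control tumors, BRAFi against vehicle in PD-L2 tumors, PD-L2 against control under vehicle, PD-L2 against control under BRAFi, the interaction (the BRAFi response of PD-L2 tumors minus that of control tumors), and the averages of both BRAFi responses and of both PD-L2 differences. The BRAFi responses of control and PD-L2 tumors share no library, while the comparisons of PD-L2 with control reuse the libraries of the BRAFi comparisons.

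The design, the gene lists, the rule for naming genes and most of the alternative settings were chosen before the data were examined. Lists of 730 genes in 39 pathways and cell types were set, of which 728 genes were in the table and 604 were tested; 36 lists had at least 5 tested members. The lymphocyte list had 2 tested members, the adipocyte list 4 and the erythroid list 4, so they were not tested. Pdcd1lg2 was left out of every list. Lists were tested with camera in limma (preset correlation 0.01, adjusted over the 36 lists of a comparison). Each list call was examined again with a correlation estimated from the list itself, which left 0 of the 76 list calls over the 7 comparisons, and with fry (statmod 1.5.0), which asks only whether a list's genes move on balance in a single direction and passed 8 lists for BRAFi in control tumors, 10 for the BRAFi average and 0 elsewhere. Members past the threshold are counted over all genes tested and also adjusted over the list alone. Some lists share members: Egr1 is in the MAPK output and immediate early lists, Adm and Vegfa are in the hypoxia and angiogenic lists, and Axl and Egfr are in the dedifferentiation and receptor tyrosine kinase lists.

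Genes were named by a rule. It takes Pdcd1lg2; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the 3 tumors of each group (all where fewer passed, and the 5 smallest p-values where none passed); up to 4 members per list with the smallest p; 29 genes set in advance; and, for the interaction, the 10 smallest p-values past the threshold. Genes named outside the rule are said to be chosen after their values were seen. Some genes that the rule takes are not reported here.

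Alternatives were another pseudocount, no filter or a filter at a mean of 5 FPKM, rescaling every library to the same sum, shifting to the same median, quantile normalization, robust empirical Bayes, sample weights from arrayWeights, a block for the replicate number, a fit to the 2 compared groups only, and leaving out each library in turn. A library left out leaves a group of 2, which is assumed to vary like the others. Removing a smooth (lowess, span 0.3) trend over transcript length or over GC content from each library, dropping small RNA genes (263 of the tested genes), and the replicate block together with the length correction were chosen after seeing the data. Transcript length and GC content came from the longest GENCODE M21 transcript of each gene, found for 12039 (99.4%) of the tested genes; these, like the RefSeq gene order used for the neighbours of Braf, belong to the GRCm38 assembly and not to mm9, so no coordinates are given. The method was tested on data simulated from the means and spreads of these libraries for BRAFi against vehicle in control tumors, over 12117 genes. It recovered 14.9% of genes changed by 0.5 on the log2 scale (10 of 67), 59.7% of those changed by 1 (40 of 67) and 92.4% of those changed by 2 (61 of 66), and it called 5 of 11900 unchanged genes. A list of 17 genes shifted by 0.5 gave camera adjusted p = 0.00988 with the preset correlation and adjusted p = 0.18 with an estimated correlation. The stricter form thus missed that simulated shift. The genes were simulated independently of each other. In the real lists the estimated correlation for BRAFi in control tumors was, for example, 0.038 for apoptosis, 0.689 for hypoxia and 0.938 for dendritic cell and MHC class II genes. The simulation therefore cannot tell which form is right for lists whose members vary together. Its gene calls were counted on values without a trend over transcript length. They give no rate of false calls for libraries that hold such a trend. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.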

Results

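RNA expression was measured in 12 YUMM1.7 tumors that differed in PD-L2 overexpression and in BRAF inhibitor treatment. PD-L2 (gene Pdcd1lg2) is a ligand of the PD-1 receptor of T cells, and the host mice lack T and B lymphocytes, so the comparisons concern what tumors with and without PD-L2 express at baseline and under BRAFi. The series design speaks of resistance to the inhibitor; the sample labels give only the treatment. Each of the 4 groups (control vehicle, control BRAFi, PD-L2 vehicle and PD-L2 BRAFi) held 3 tumors. Depth is unknown, because the table holds FPKM and no read counts. FPKM sums ran from 499845 in control BRAFi tumor 1 to 648254 in PD-L2 BRAFi tumor 2, and 16269 to 17469 genes were above 0. In PD-L2 BRAFi tumor 2 the microRNA gene Mir2137 took 16.13% of the summed FPKM and was listed at 0 in the other 11 libraries; genes of small RNAs took 21.87% of that library and 2.94 to 7.63% of the others. The same library had the lowest values of the Y-linked genes, with Ddx3y at 3.6 FPKM against 9.97 to 29.5 in the others. Spearman correlations between libraries were 0.948 to 0.969 within groups and 0.941 to 0.968 between groups, and no 2 libraries held identical values.

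Pdcd1lg2, the introduced gene, was first compared across groups. Its mean was 0.192 ± 0.0765 FPKM in control vehicle tumors and 71.2 ± 38.2 FPKM in PD-L2 vehicle tumors (SD, n = 3 each). Under BRAFi it was 1.77 ± 1.54 FPKM in control and 123 ± 88.5 FPKM in PD-L2 tumors. The lowest PD-L2 library, PD-L2 BRAFi tumor 2 with 20.8 FPKM, lay above the highest control library, control BRAFi tumor 2 with 3.54 FPKM, so the levels follow the labels in 12 of 12 libraries. The log2 fold change of PD-L2 over control tumors was 5.11 ± 0.72 under BRAFi (SE, limma adjusted p = 0.0454) and 5.45 ± 0.51 over both treatments (adjusted p = 0.00233). Under vehicle it was 5.80 ± 0.72 and missed the threshold (adjusted p = 0.0521). Under BRAFi the fold change was 4.60 to 6.34 over 27 alternatives and passed in 8. The call ended without any 1 library except PD-L2 BRAFi tumor 2 (6.12 without it, 4.60 to 5.54 without each of the others). Under vehicle it was 5.39 to 7.83 and passed in 7 of 27. Among these, a fit to the 2 vehicle groups only gave 5.80 ± 0.36 (limma adjusted p = 0.013). Without PD-L2 BRAFi tumor 2, which is not in this comparison, it was 5.80 ± 0.40 (limma adjusted p = 0.00129). The miss under vehicle therefore came with the spread shared by the 4 groups, while the fold change stayed the same. BRAFi against vehicle did not pass for Pdcd1lg2 in control (1.08 ± 0.72, adjusted p = 0.317) or PD-L2 tumors (0.40 ± 0.72, adjusted p = 0.784). In control tumors the values did not overlap all the same, at 0.133 to 0.278 FPKM under vehicle and 0.863 to 3.54 under BRAFi (ratio of means 9.22). The pseudocount of 1 understates such low values; with 0.1 the change was 2.41 ± 0.79 (adjusted p = 0.0736).

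**Figure D1:**
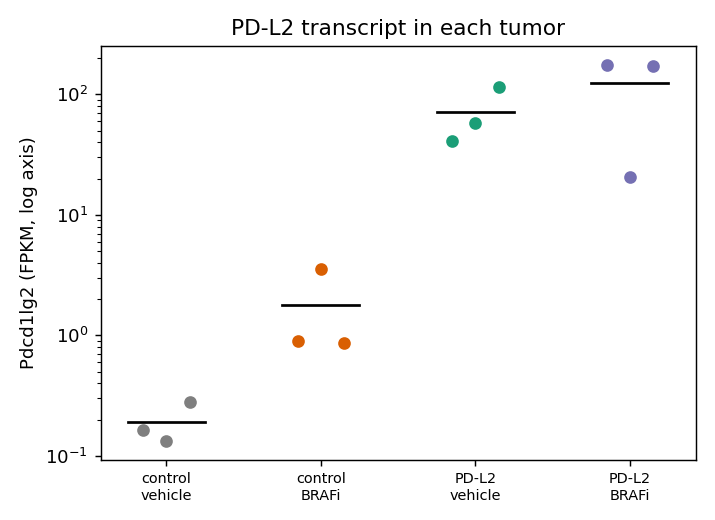
Pdcd1lg2 FPKM (log axis) in each of the 3 tumors of the 4 groups, with a line at each group mean. All 6 PD-L2 tumors, from 20.8 to 176 FPKM, lie above all 6 control tumors, of which the highest is at 3.54 FPKM.

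BRAFi was compared with vehicle in control tumors to ask what the treatment does without added PD-L2. The neuropeptide Npy had the largest of the rises that the rule names, 4.41 ± 1.10 on the log2 scale, from 0.237 ± 0.198 to 80.6 ± 125 FPKM (SD, n = 3 each; adjusted p = 0.0429). The mast cell protease Mcpt1 rose by 4.33 ± 0.61 (adjusted p = 0.0209) and the calcium channel subunit Cacng3 by 4.19 ± 0.49 (adjusted p = 0.0182). Nppb, a natriuretic peptide precursor (4.18 ± 1.08), the collagenase Mmp1a (3.63 ± 0.70) and Pthlh, a parathyroid-hormone-like factor (3.54 ± 0.86), rose as well, with adjusted p from 0.0301 to 0.046. So did the prolactin family members Prl2c3 (4.12 ± 1.07) and Prl8a9 (3.79 ± 0.92), Plet1 (3.73 ± 0.85) and Dynap (3.99 ± 1.04), with adjusted p from 0.0385 to 0.0467. Several rises were uneven between tumors: Npy was at 225, 5.4 and 11.2 FPKM in the 3 BRAFi tumors. Hemoglobin genes were among the largest falls. Hbb-b1 fell by 2.46 ± 0.34, from 116 ± 34.6 to 19.8 ± 2.88 FPKM (adjusted p = 0.0209), and Hba-a1 by 2.25 ± 0.36 (adjusted p = 0.0277), with Hbb-b2 at -2.20 ± 0.31 and Hbb-bs at -4.27 ± 0.87. The folate receptor Folr2 (-1.76 ± 0.33, adjusted p = 0.0301) and the chemokine Pf4 (-1.93 ± 0.42, adjusted p = 0.0354) also fell. Gas6, a ligand of Axl-family receptors (-1.69 ± 0.37, adjusted p = 0.0354), and the carbonyl reductase Cbr2 (-1.97 ± 0.46, adjusted p = 0.0396) fell too. The small RNA genes Rnu12 (20.1, 15.9 and 14.9 FPKM) and Mir680-2 (15.3, 6.54 and 12.6 FPKM) under vehicle were listed at 0 in all 3 BRAFi tumors. In each of these genes the 3 tumors of the 2 groups did not overlap, which the rule for naming them requires.

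In all, 899 of 12117 genes passed, 425 higher and 474 lower, against 3858 at an unadjusted p under 0.05, of which 606 would be expected by chance. The groups did not overlap for 36.1% of genes, where chance gives 10% for 3 against 3. Rescaling to the same sum, which moved the median of all genes by 0.16, called 1196 higher and 240 lower. The count depended on single libraries. It was 2, 0 and 1649 without control vehicle tumors 1, 2 and 3, and 413, 4 and 81 without control BRAFi tumors 1, 2 and 3. It was 183, 17 and 448 without PD-L2 vehicle tumors 1, 2 and 3, and 123 without PD-L2 BRAFi tumor 1. Every single-gene call in control tumors therefore ended without control vehicle tumor 2, and at most 4 genes passed without control vehicle tumor 1 or control BRAFi tumor 2. Among the genes set in advance, 4 passed. Spry4, a feedback inhibitor of MAPK signalling, rose by 1.40 ± 0.21 (27.8 ± 5.12 to 76.6 ± 24.1 FPKM, adjusted p = 0.0267). Braf, the target of the inhibitor, rose by 1.93 ± 0.34 (3.61 ± 1.14 to 18.1 ± 10.6 FPKM, adjusted p = 0.0288), and with the length trend removed its change was 1.53 and missed the threshold. It was at 15.3, 29.7 and 9.14 FPKM in the 3 BRAFi tumors, and in the second of these its 4 nearest tested genes on each side had a median 1.25 above the control vehicle mean (log2), with 5 of the 8 higher. Cd274, which encodes PD-L1, rose by 0.98 ± 0.24 (2.43 ± 0.27 to 5.78 ± 0.858 FPKM, adjusted p = 0.0398) and the growth factor receptor Pdgfra by 0.58 ± 0.15 (adjusted p = 0.0464). Dusp6 (0.81 ± 0.22, adjusted p = 0.0513), Egfr (0.94 ± 0.29, adjusted p = 0.0627) and the melanocyte regulator Mitf (0.08, adjusted p = 0.774) did not pass. Dct and Mlana were near 0 and Tyr at 0.688 to 1.11 FPKM, below the filter.

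**Figure D2:**
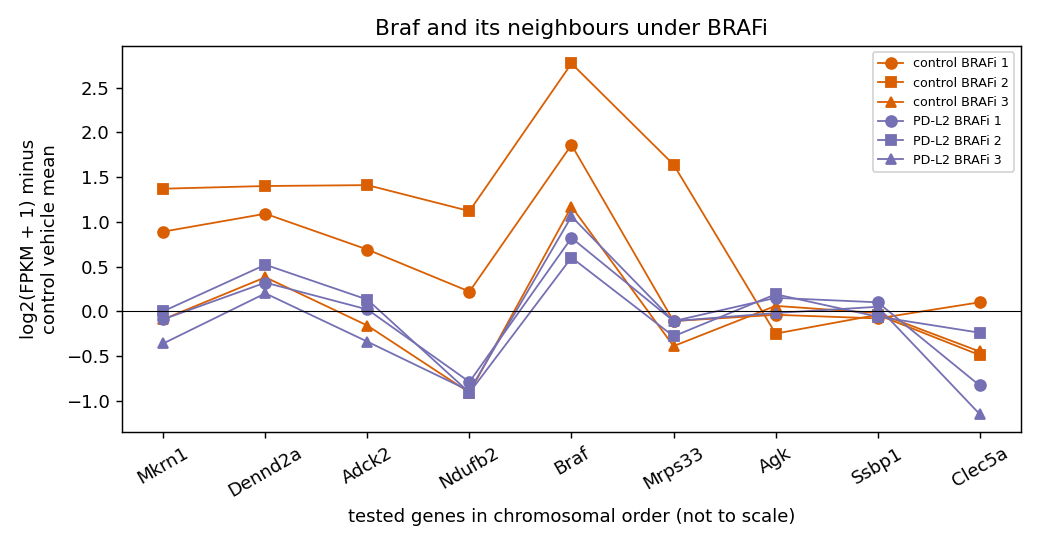
Difference from the control vehicle mean (log2 scale, vertical axis) of Braf and its 4 nearest tested genes on each side, in genomic order (horizontal axis), 1 line for each of the 6 BRAFi tumors. Braf lies 1.86, 2.77 and 1.17 above that mean in control BRAFi tumors 1, 2 and 3, and in tumor 2 the median of its neighbours is 1.25.

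Several gene lists were higher under BRAFi in control tumors with the preset correlation, and none passed with an estimated correlation. The MAPK output list, targets and feedback inhibitors of ERK, was higher (median 0.81 over 19 members, camera adjusted p = 4.3e-06; adjusted p = 0.726 with an estimated correlation). In it Spry4, Spred1 (0.95 ± 0.15), Egr1 (1.95 ± 0.43) and Myc (0.88 ± 0.23) rose, 4 members over all genes and 14 adjusted over the list alone. Immediate early genes were higher (median 0.61, adjusted p = 0.00178; adjusted p = 0.726 with an estimated correlation), with Egr3 (2.87 ± 0.35), Jun (0.58 ± 0.11), Fosb (1.18 ± 0.26) and Egr1 past the threshold, and 5 adjusted over the list alone. The dedifferentiation and mesenchymal list had a median of 0.55 (adjusted p = 0.00178; adjusted p = 0.726 with an estimated correlation); Zeb1 (0.78 ± 0.16) and Prrx1 (0.41 ± 0.09) rose, and 9 rose and 1 fell adjusted over the list alone. Extracellular matrix genes had a median of 0.46 (adjusted p = 0.00377; adjusted p = 0.884 with an estimated correlation). In this list 4 rose, Timp3 (0.69 ± 0.11), Lamb1 (0.57 ± 0.14), Col4a2 (0.99 ± 0.25) and Thbs1 (1.54 ± 0.40), against 8 adjusted over the list alone. Receptor tyrosine kinases (median 0.34, adjusted p = 0.0227) had 1 riser, Pdgfra, and 6 adjusted over the list alone. YAP targets (median 0.32, adjusted p = 0.0357) had 2, Myof (1.22 ± 0.25) and Tead1 (0.91 ± 0.22), and 4 adjusted over the list alone. Both gave adjusted p = 0.726 with an estimated correlation. The YAP call ended without control vehicle tumor 2 (median 0.30) or control BRAFi tumor 3 (0.33) and after rescaling to the same sum (0.50).

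Cytosolic ribosomal protein genes were lower under BRAFi (median -0.60 over 29 members, adjusted p = 1.11e-11; adjusted p = 0.726 with an estimated correlation). Of these, 13 fell over all genes and 23 adjusted over the list alone, such as Rplp1 (-0.78 ± 0.15), Rpl13 (-0.79 ± 0.16) and Rps14 (-1.03 ± 0.23); quantile normalization moved the median to -0.11. Oxidative phosphorylation genes followed (median -0.42 over 34 members, adjusted p = 2.93e-09; adjusted p = 0.726 with an estimated correlation), with 12 fallers. These include Ndufb8 (-0.97 ± 0.16), Ndufa1 (-0.70 ± 0.11) and Atp5j (-0.62 ± 0.11); 21 fell and 1 rose adjusted over the list alone, and the median was -0.24 after rescaling to the same sum. Macrophage markers had a median of -0.74 (adjusted p = 0.00477; adjusted p = 0.898 with an estimated correlation) with no member past the threshold, including the lysozyme Lyz2 (-1.92 ± 0.58, adjusted p = 0.062) and Cd68 (-0.86 ± 0.28, adjusted p = 0.0761). The macrophage call ended without control BRAFi tumor 2 (median -0.37). The log2 fold change correlated with length across genes (Spearman 0.456 over 12039 genes, which are not independent) and with GC content (-0.307). Genes called higher had a median length of 5248 nt and those called lower 1498 nt, and ribosomal protein genes have a median of 1120 nt. In 5 equal bins of length, the shortest genes had a median change of -0.280 and the longest 0.308. With the length trend removed, 28 genes passed (18 higher and 10 lower), and list medians were -0.24 for ribosomal proteins, -0.12 for oxidative phosphorylation, 0.81 for MAPK output, 0.19 for extracellular matrix, 0.06 for receptor tyrosine kinases and 0.23 for YAP targets. The calls of the last 2 lists ended, and the other 4 lists passed; with the replicate block as well, the oxidative phosphorylation and extracellular matrix calls ended too.

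**Figure D3:**
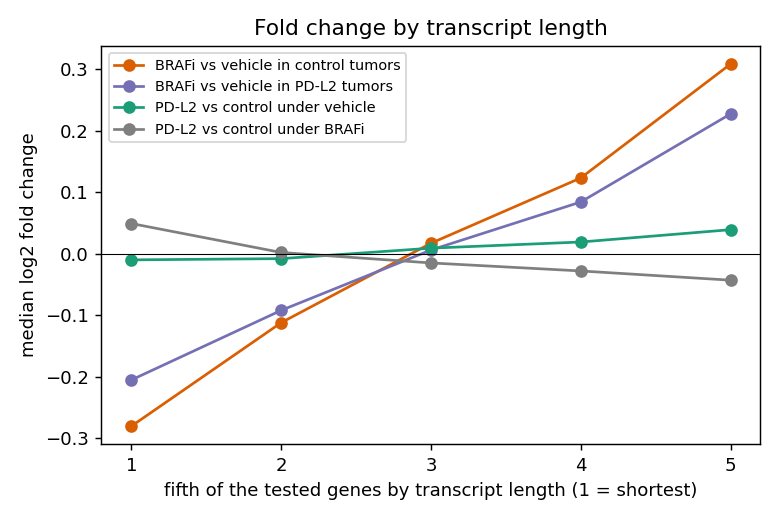
Median log2 fold change of the tested genes (vertical axis) in 5 equal bins of transcript length from shortest to longest (horizontal axis), 1 line for each of the 4 comparisons of 2 groups. Both BRAFi comparisons run upward, from -0.280 to 0.308 in control and from -0.205 to 0.227 in PD-L2 tumors, while the medians of both PD-L2 comparisons stay within 0.049 of 0; trends over GC content are not drawn.

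Other lists in control tumors did not pass, although single members did. Lef1 (0.73 ± 0.19) and Tcf7 (1.34 ± 0.29), transcription factors of the beta-catenin list, rose (list median 0.36, adjusted p = 0.0954). Cdh19 (1.32 ± 0.32) rose within a Schwann cell and neural crest list that did not pass (0.13, adjusted p = 0.561). Il10 rose (2.33 ± 0.47) and Folr2 fell within the alternative macrophage list (-0.32, adjusted p = 0.278). Flt1 rose in the endothelial list (1.56 ± 0.38; median -0.36, adjusted p = 0.561), Cspg4 in the pericyte list (1.22 ± 0.23; 0.19, adjusted p = 0.583), Il1r2 in the neutrophil list (0.93 ± 0.24; 0.12, adjusted p = 0.583) and Inhba in the TGF-beta list (1.68 ± 0.38; 0.22, adjusted p = 0.386). Gins2 (-0.72 ± 0.11) and Tyms (-0.43 ± 0.12) fell in the DNA replication list (-0.15, adjusted p = 0.0608), and Birc5 in the mitosis list (-0.52 ± 0.13; 0.06, adjusted p = 0.839). The survival genes Bcl2l1 (0.61 ± 0.14), Bcl2l2 (0.50 ± 0.12) and Xiap (0.60 ± 0.15) rose within an apoptosis list that did not pass (-0.03, adjusted p = 0.892). Cholesterol synthesis (0.48, adjusted p = 0.0517), MHC class I presentation (-0.52, adjusted p = 0.0608), skeletal muscle (-1.64, adjusted p = 0.104), type I interferon (-0.38, adjusted p = 0.114) and dendritic cell and MHC class II genes (0.24, adjusted p = 0.78) did not pass. The checkpoint list, to which Cd274 belongs, had a median of -0.07 but a mean of 0.22 and an upward test (adjusted p = 0.583). Adjusted over the list alone, 3 pericyte, 3 TGF-beta and 2 neutrophil members rose, 5 DNA replication and 0 mitosis members fell, and 4 apoptosis members rose and 1 fell.

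BRAFi was compared with vehicle in PD-L2 tumors in the same way. Mmp9, a gelatinase that degrades basement membrane, rose by 3.40 ± 0.32, from 12.6 ± 4.4 to 139 ± 21.1 FPKM (SD, n = 3 each; adjusted p = 0.00216), and it kept its call in all 27 alternatives. Other genes that rose were Itga1, an integrin subunit (1.88 ± 0.23, adjusted p = 0.0148), the proteoglycan Vcan (1.84 ± 0.30) and the collagens Col15a1 (1.82 ± 0.30; both adjusted p = 0.0452) and Col4a1 (1.61 ± 0.24, adjusted p = 0.0367). Tgfb2, a TGF-beta ligand (1.51 ± 0.17, adjusted p = 0.0111), and the matricellular gene Postn (1.62 ± 0.26, adjusted p = 0.0452) rose in a TGF-beta list that did not pass (median 0.10, adjusted p = 0.154). The Wnt antagonist Nkd2 (1.93 ± 0.27), the transcription factor Prdm1 (1.82 ± 0.27) and the neuropeptide Gal (2.87 ± 0.47) rose with adjusted p from 0.028 to 0.0452. The largest falls were in Spon2, an extracellular matrix protein (-2.34 ± 0.31, from 11.5 to 1.48 FPKM, adjusted p = 0.0197), and Tmem200b (-1.34 ± 0.18, adjusted p = 0.0263), followed by Crlf2 (-0.96 ± 0.16), Ptrf (-0.85 ± 0.14), Hspb6 (-0.71 ± 0.09), Arhgef19 (-0.68 ± 0.12) and Leprel4 (-0.65 ± 0.10). The microRNA gene Mir212 was at 18.2, 14.8 and 18.5 FPKM in the 3 PD-L2 BRAFi tumors and Mir1940 at 11.5, 9.33 and 12.9, and both were listed at 0 in the other 9 libraries; Mir8104 was at 8.24, 15.8 and 21.2 FPKM. FPKM of such short genes is an unstable estimate in poly(A)-selected libraries. No gene set in advance passed; Spry4 was 1.16 ± 0.21 (32 ± 1.53 to 73.1 ± 9.46 FPKM, adjusted p = 0.0543) and Braf 0.61 ± 0.34 (adjusted p = 0.329).

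In PD-L2 tumors 29 genes passed, 22 higher and 7 lower, with 2586 at an unadjusted p under 0.05 and no overlap for 29.9% of genes (10% by chance). Rescaling to the same sum called 14 higher and 2 lower, and quantile normalization 28 and 18. The count was 136, 9 and 11 without control vehicle tumors 1, 2 and 3, 48 without control BRAFi tumor 2, 9, 3 and 4 without PD-L2 vehicle tumors 1, 2 and 3, and 5 and 4 without PD-L2 BRAFi tumors 2 and 3. The control libraries enter only through the shared estimate of spread.

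Lists moved in PD-L2 tumors mostly without members past the threshold. The MAPK output list was higher (median 0.47, adjusted p = 0.00091; adjusted p = 0.591 with an estimated correlation), with 0 members past the threshold and 5 adjusted over the list alone. Extracellular matrix genes were higher (0.50, adjusted p = 2.21e-05; adjusted p = 0.591 with an estimated correlation), where Col4a1 and Vcan rose and 9 members did so adjusted over the list alone; the median was 0.29 without PD-L2 vehicle tumor 3 and 0.33 with the length trend removed. Pericyte markers had a median of 0.73 (adjusted p = 0.0162; adjusted p = 0.591 with an estimated correlation), with Rgs5 at 1.90 ± 0.42 (adjusted p = 0.0745), 0 members past and 3 adjusted over the list alone; the call ended with a filter at a mean of 5 FPKM (0.58) and in a fit to the 2 groups only (0.73). Hypoxia genes (0.52, adjusted p = 0.00781; adjusted p = 0.823 with an estimated correlation) had 0 members past on either count, and the call ended without PD-L2 BRAFi tumor 1 (0.37). The beta-catenin list (0.22, adjusted p = 0.0144; adjusted p = 0.591 with an estimated correlation) had 1 riser, Nkd2, and 4 risers and 1 faller adjusted over the list alone. Its median was 0.70 without PD-L2 BRAFi tumor 3 and 0.34 without PD-L2 vehicle tumor 3, 0.60 with a filter at a mean of 5 FPKM and 0.34 with the length trend removed. Its call ended in a fit to the 2 groups only. YAP targets (0.23, adjusted p = 0.0251; adjusted p = 0.591 with an estimated correlation) had 0 past and 2 adjusted over the list alone. Their call ended without PD-L2 vehicle tumor 1 (0.16) or 3 (0.21), without PD-L2 BRAFi tumor 3 (0.21) and with the length trend removed (0.09).

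Oxidative phosphorylation genes were lower in PD-L2 tumors (median -0.28, adjusted p = 3.28e-06; adjusted p = 0.591 with an estimated correlation; 6 adjusted over the list alone), as were ribosomal protein genes (-0.30, adjusted p = 2e-05; adjusted p = 0.823 with an estimated correlation; 0 adjusted over the list alone). DNA replication genes were lower (-0.24, adjusted p = 2e-05; adjusted p = 0.591 with an estimated correlation; 6 adjusted over the list alone), with the helicase subunit Mcm5 at -0.43 ± 0.11 (adjusted p = 0.0944). Mitosis genes were lower (-0.20, adjusted p = 0.000412; adjusted p = 0.823 with an estimated correlation; 3 adjusted over the list alone), with Birc5 at -0.63 ± 0.13 (adjusted p = 0.068) and a median of -0.10 without PD-L2 vehicle tumor 3. No member of these 4 lists passed over all genes. Fold changes again followed transcript length (Spearman 0.413 across genes) and GC content (-0.382). With the GC trend removed 11 genes passed, 10 of them among the 29 main calls. Whether the changes that lost their call became smaller or only missed the threshold is not given here. With the length trend removed, the oxidative phosphorylation (-0.07) and ribosomal (-0.06) calls ended, and the ribosomal call also ended under quantile normalization (-0.09).

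**Figure D4:**
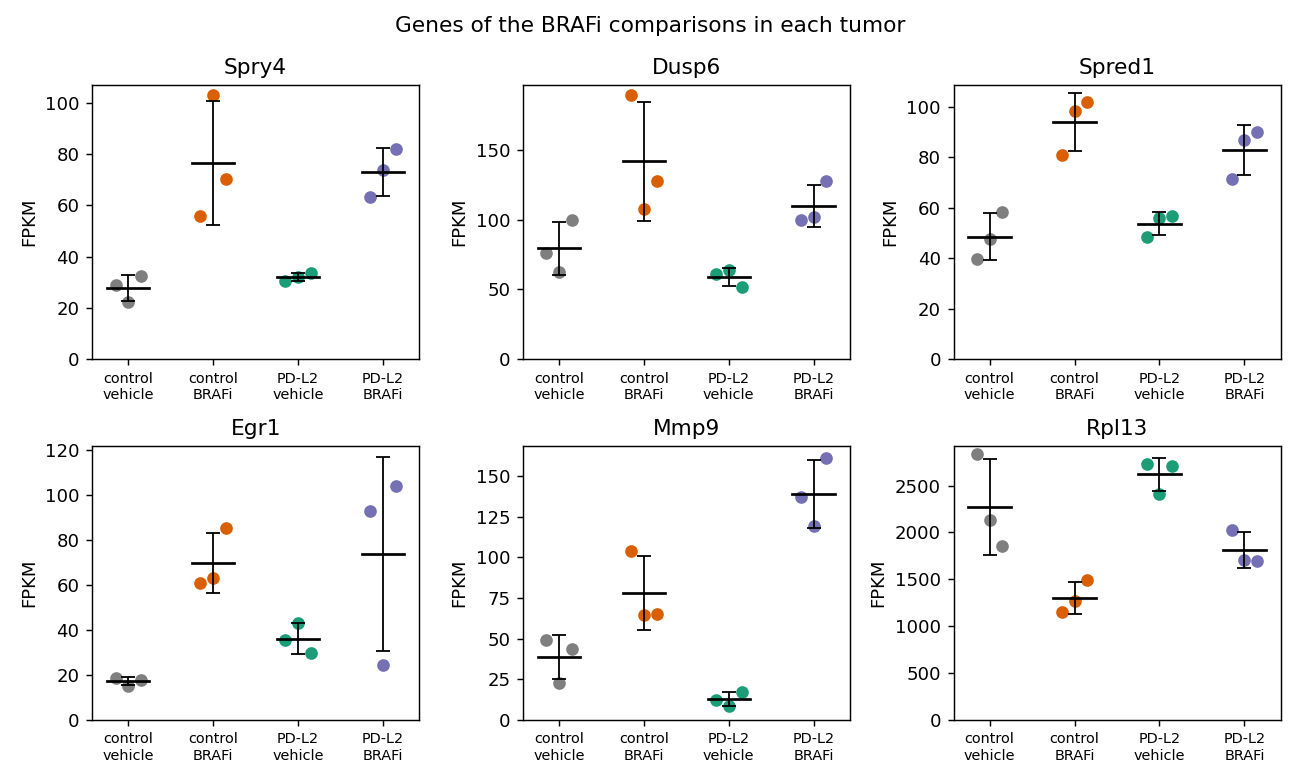
FPKM of Spry4, Dusp6, Spred1, Egr1, Mmp9 and Rpl13 (1 panel each) in the 3 tumors of each of the 4 groups; points are tumors, lines are means and bars are SDs. Spry4 is at 22.2 to 33.5 FPKM in the 6 vehicle tumors and at 56 to 103 FPKM in the 6 BRAFi tumors.

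The BRAFi responses of control and PD-L2 tumors were then set against each other. Across the 12117 genes the fold changes correlated (Pearson 0.521, Spearman 0.648; genes are not independent and the responses share no library), with a slope of 0.443 for PD-L2 on control tumors. Of the 899 genes called in control tumors, 872 (97.0%) had the same sign in PD-L2 tumors, against 76.4% of all genes. Their median change in the direction seen in control tumors was 0.70 in control and 0.42 in PD-L2 tumors. These genes were selected for their change in control tumors, so a smaller median in PD-L2 tumors is expected even of equal responses. Noise in the control fold changes likewise lowers the slope. Neither value shows a weaker response in PD-L2 tumors. Calls shared by both were 5 risers (0.8 expected of independent lists) and 4 fallers (0.3 expected). They include Enpp2, which makes the lipid mediator lysophosphatidic acid (1.94 in control and 1.21 in PD-L2 tumors), Gpm6b (1.29 and 1.74) and Spon2 (-1.63 and -2.34), chosen among the 9 after their values were seen. Both tests use the same estimate of each gene's spread, and both responses follow transcript length. The lists of calls are therefore not independent, and the excess over the expected numbers is not a replication. The different numbers of calls do not show different responses. The interaction passed for 2 genes in limma, the microRNA genes Mir212 and Mir1940, with 542 at an unadjusted p under 0.05, which is below the 606 expected by chance. That count was 3 without control vehicle tumor 1 or 3, 5 without control BRAFi tumor 3, 5 without PD-L2 vehicle tumor 1, 4 without PD-L2 BRAFi tumor 1 and 3 without PD-L2 BRAFi tumor 2.

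The effect of BRAFi was also averaged over both backgrounds. Spry4 rose by 1.28 ± 0.15 (adjusted p = 0.00424), Dusp6, a phosphatase of ERK, by 0.85 ± 0.16 (adjusted p = 0.00858), the growth factor receptor Egfr by 1.11 ± 0.20 (adjusted p = 0.00846) and the immediate early factor Egr3 by 2.17 ± 0.25 (adjusted p = 0.00424). The average effect of BRAFi passed for 2988 genes, 1626 higher and 1362 lower (4889 unadjusted; 2206 and 773 after rescaling to the same sum). The count was 1755 without control vehicle tumor 1, 1355 and 1928 without PD-L2 vehicle tumors 1 and 2 and 1734 without PD-L2 BRAFi tumor 3. With the length trend removed 1480 passed, 774 higher and 706 lower. In the MAPK output list 11 of 19 members rose (median 0.55, adjusted p = 1.9e-05; adjusted p = 0.607 with an estimated correlation). In the extracellular matrix list 12 rose, such as Col4a1 (1.24 ± 0.17) and Col4a2 (1.20 ± 0.18) (0.49, adjusted p = 0.00018; adjusted p = 0.681 with an estimated correlation; 0.32 with the length trend removed). Of the ribosomal protein genes 21 of 29 fell (-0.44, adjusted p = 1.61e-09; adjusted p = 0.681 with an estimated correlation), a call that ended under quantile normalization (-0.11) and had a median of -0.16 with the length trend removed. Of the oxidative phosphorylation genes 24 of 34 fell (-0.36, adjusted p = 8.89e-09; adjusted p = 0.635 with an estimated correlation; -0.10 with the length trend removed). DNA replication genes were lower (-0.21, adjusted p = 0.00135; adjusted p = 0.681 with an estimated correlation), where 8 fell, such as Gins2 (-0.54 ± 0.08), and rescaling to the same sum gave -0.11. Adjusted over the list alone, 14 MAPK output and 13 extracellular matrix members rose. On that count 23 ribosomal and 9 DNA replication members fell, as did 27 oxidative phosphorylation members against 2 that rose.

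The dedifferentiation and mesenchymal list was also higher in the average (0.37, adjusted p = 0.00662; adjusted p = 0.681 with an estimated correlation), where 9 rose, such as Egfr and the Wnt ligand Wnt5a (1.04), and 1 fell. Macrophage markers were lower (-0.56, adjusted p = 0.00867; adjusted p = 0.836 with an estimated correlation), and Lyz2 (-1.65 ± 0.41, adjusted p = 0.0192) and Cd68 (-0.70 ± 0.20, adjusted p = 0.031) fell. The macrophage median was -0.34 without control BRAFi tumor 2 and -0.33 without PD-L2 BRAFi tumor 3. Beta-catenin targets were higher (0.32, adjusted p = 0.0205; adjusted p = 0.607 with an estimated correlation), with 4 risers such as Lef1 (0.85 ± 0.14) and Nkd2 (1.14), and the call ended without control BRAFi tumor 2 (0.27) and with no filter (0.08). The beta-catenin median was 0.76 with a filter at a mean of 5 FPKM and 0.60 with a pseudocount of 0.1. YAP targets (0.25, adjusted p = 0.0125; adjusted p = 0.607 with an estimated correlation) had 5 risers and lost the call with the length trend removed (0.12). Receptor tyrosine kinases (0.28, adjusted p = 0.0212; adjusted p = 0.607 with an estimated correlation) had 3, Egfr, Pdgfra (0.45) and Pdgfrb (0.64 ± 0.18), and lost it likewise (0.07). Hypoxia genes (0.48, adjusted p = 0.0154; adjusted p = 0.836 with an estimated correlation) had 2 risers, Mxi1 (1.03 ± 0.23) and Vegfa (0.60 ± 0.20), and the call ended without control BRAFi tumor 2 (0.32) or PD-L2 BRAFi tumor 1 (0.41). Immediate early genes (0.39, adjusted p = 0.0212; adjusted p = 0.836 with an estimated correlation) had 4 risers and 1 faller, and the call ended without control BRAFi tumor 3 (0.29) or PD-L2 BRAFi tumor 1 (0.31) and after rescaling to the same sum (0.49). Adjusted over the list alone, the dedifferentiation list had 11 risers and 1 faller, the immediate early list 8 and 1, the macrophage list 1 faller and the hypoxia list 1 riser. The beta-catenin, YAP and receptor tyrosine kinase counts were unchanged.

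**Figure D5:**
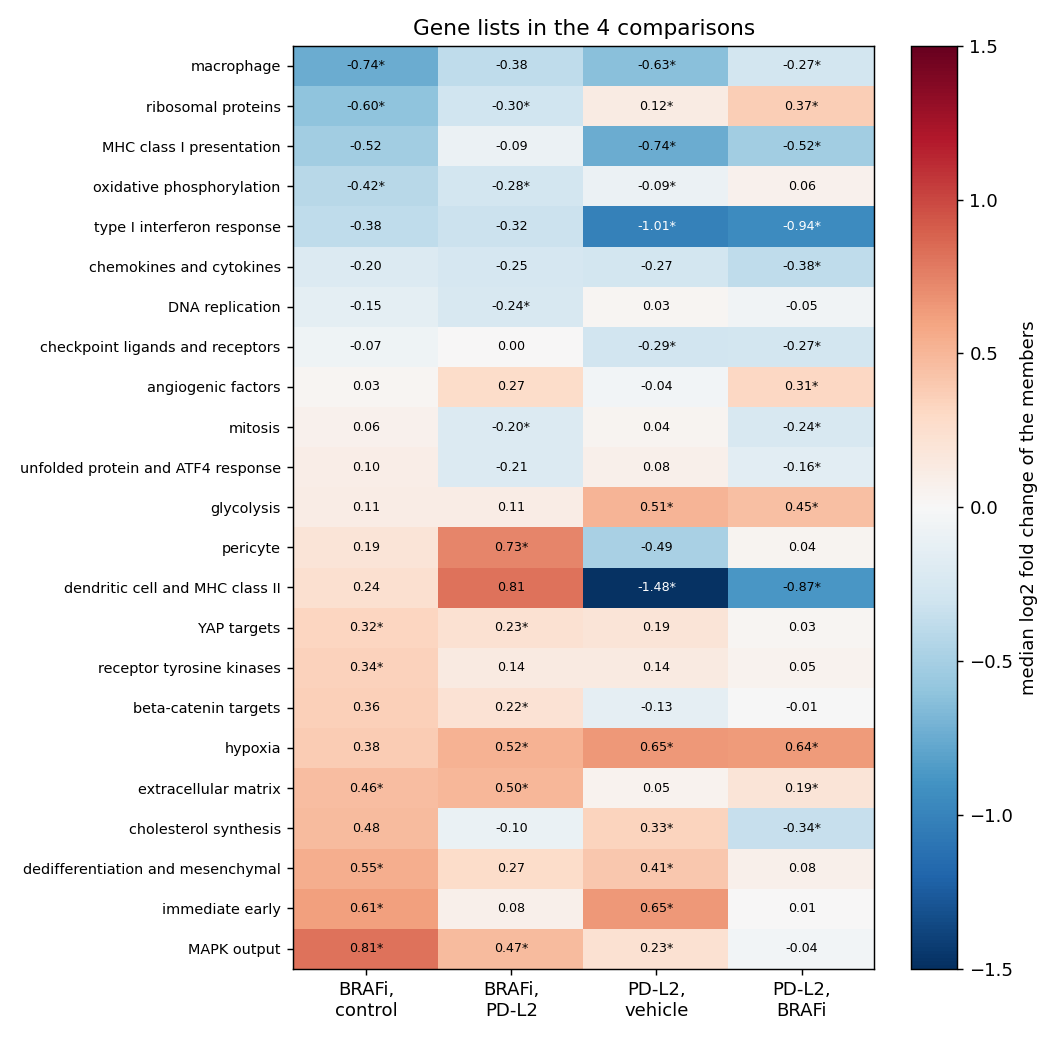
Median log2 fold change of the members (colour and number) of the 23 lists called in at least 1 of the 4 comparisons of 2 groups (columns); an asterisk marks a camera adjusted p under 0.05 with the preset correlation, and no list passed with an estimated correlation. MAPK output is 0.81 and 0.47 under BRAFi in control and PD-L2 tumors, and type I interferon response is -1.01 and -0.94 in PD-L2 against control tumors under vehicle and BRAFi.

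PD-L2 tumors were compared with control tumors under vehicle to ask what accompanies PD-L2 overexpression at baseline. Interferon, antigen presentation and macrophage genes had lower values and hypoxia and glycolysis genes higher values in PD-L2 tumors, while no single gene passed. The type I interferon list was lower (median -1.01, 25 of 25 members lower, adjusted p = 8.88e-07), with the antiviral genes Oas1a at -1.41 ± 0.62 (adjusted p = 0.442) and Ifih1 at -1.10. MHC class I presentation was lower (-0.74, 16 of 16 members, adjusted p = 4.19e-06), with the immunoproteasome subunit Psmb9 at -1.51 ± 0.59. Dendritic cell and MHC class II genes had a median of -1.48 (7 of 7 members lower, adjusted p = 0.000792), with H2-Aa at -1.72 ± 0.69 and Cd74 at -1.70 ± 0.76. Hypoxia genes were higher (0.65, 19 of 19 members, adjusted p = 1.27e-05), with the angiogenic factor Vegfa at 1.01 ± 0.28 and the carbonic anhydrase Car9 at 1.41 ± 0.52. Glycolysis genes were higher (0.51, 17 of 18 members, adjusted p = 5.02e-06), with Gapdh at 0.56 ± 0.17, and immediate early genes were higher (0.65, adjusted p = 2.1e-06), with Jun at 0.52 ± 0.11. Each of these 6 lists gave adjusted p = 0.592 with an estimated correlation. None had a member past the threshold over all genes, and adjusted over the list alone the immediate early list had 3. Without control vehicle tumor 1 the medians were 0.35 for hypoxia and 0.32 for glycolysis, and without control vehicle tumor 2 that for hypoxia was 1.03. With no filter the dendritic cell and MHC class II median was -0.37.

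In limma 0 genes passed under vehicle, against 1319 at an unadjusted p under 0.05, and the groups did not overlap for 20.6% of genes (10% by chance). The introduced gene Pdcd1lg2 missed the threshold too, so a count of 0 does not show that no gene differs. The smallest p-values belonged to Nkd2 (-2.22 ± 0.27, 9.68 ± 2.1 FPKM in control and 1.28 ± 0.254 in PD-L2 tumors, adjusted p = 0.0521), Pdcd1lg2, the poly(A)-binding protein Pabpc4 (0.71 ± 0.10, adjusted p = 0.0786), the semaphorin Sema3b (1.55 ± 0.23, adjusted p = 0.111) and Postn (-1.71 ± 0.26, 399 ± 29.8 and 128 ± 51.8 FPKM, adjusted p = 0.116). The same PD-L2 vehicle tumors gave the rises of Nkd2 and Postn under BRAFi described above, so these differences are not separate results. The count was 1 without control vehicle tumor 1, control BRAFi tumor 1, PD-L2 BRAFi tumor 1 or PD-L2 BRAFi tumor 3, 2 without PD-L2 BRAFi tumor 2 and 3 without PD-L2 vehicle tumor 1. Fold changes correlated with GC content (Spearman 0.224 across genes) more than with length (0.090), and 1 gene passed with the GC trend removed.

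A further 7 lists passed under vehicle with 0 members past the threshold. Macrophage markers were lower (-0.63, 19 of 20 members, adjusted p = 0.000135; adjusted p = 0.592 with an estimated correlation), a call that ended without PD-L2 vehicle tumor 3 (-0.30). The dedifferentiation list was higher (0.41, adjusted p = 0.000918; adjusted p = 0.592 with an estimated correlation), although its smallest p belonged to Wnt5a at -1.53 ± 0.31, and 1 rose and 1 fell adjusted over the list alone. Cholesterol synthesis (0.33, adjusted p = 0.0191; adjusted p = 0.725 with an estimated correlation) lost its call without control vehicle tumor 1 (0.30) or 3 (0.24) or PD-L2 vehicle tumor 3 (-0.02), and was 0.54 without PD-L2 vehicle tumor 1. MAPK output (0.23, adjusted p = 0.0282; adjusted p = 0.592 with an estimated correlation) lost it without control vehicle tumor 1 (0.18) or 2 (0.19) or PD-L2 vehicle tumor 3 (0.12), with a filter at a mean of 5 FPKM (0.23) and under quantile normalization (0.19). Checkpoint genes (-0.29, adjusted p = 0.0376; adjusted p = 0.592 with an estimated correlation) lost it without control vehicle tumor 1 (-0.33) or 3 (-0.23), control BRAFi tumor 3 (-0.29) or PD-L2 vehicle tumor 1 (-0.34) or 3 (-0.20). The checkpoint call also ended with a filter at a mean of 5 FPKM (-0.12), after rescaling to the same sum (-0.33) and with the length trend removed (-0.28), and the median was -0.17 with no filter. Ribosomal proteins (0.12, adjusted p = 0.0376; adjusted p = 0.821 with an estimated correlation) lost it without control vehicle tumor 3 (-0.05), control BRAFi tumor 2 (0.12) or PD-L2 vehicle tumor 1 (0.10) or 3 (0.03). They were 0.22 and 0.20 without control vehicle tumor 1 and PD-L2 vehicle tumor 2, and 0.07 after rescaling to the same sum. The ribosomal call also ended under quantile normalization (-0.00), with the GC trend removed (0.08), with a filter at a mean of 5 FPKM and in a fit to the 2 groups only (both 0.12). Oxidative phosphorylation (-0.09, adjusted p = 0.0376; adjusted p = 0.758 with an estimated correlation) lost it without control vehicle tumor 1 (-0.01), PD-L2 vehicle tumor 1 (-0.09) or 2 (-0.08) or PD-L2 BRAFi tumor 2 (-0.09), in a fit to the 2 groups only (-0.09) and with the length trend removed (-0.06). It was -0.16 without control vehicle tumor 3 and -0.14 after rescaling to the same sum.

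PD-L2 tumors were compared with control tumors under BRAFi to ask whether they differ during treatment. Hemoglobin genes were higher in PD-L2 tumors: Hba-a1 by 2.47 ± 0.36, Hbb-b1 by 2.38 ± 0.34 (19.8 ± 2.88 FPKM in control and 109 ± 29.5 in PD-L2 tumors, SD, n = 3 each) and Hbb-b2 by 2.18 ± 0.31. The same control BRAFi tumors gave the fall of these genes against control vehicle tumors described above, so this difference is not a separate result. The transcription factor Zfp503 was higher by 0.97 ± 0.14. The potassium channel Kcnk3 was lower (-2.05 ± 0.29, 5.96 ± 3.22 in control and 0.569 ± 0.0826 FPKM in PD-L2 tumors), as was Dnajc3, a chaperone of the endoplasmic reticulum (-0.78 ± 0.11, 41.9 ± 0.639 and 24 ± 1.83 FPKM). Each of these 6 genes and Pdcd1lg2 had an adjusted p of 0.0454. With Mir212 and Mir1940 they make 9 genes past the threshold, 7 higher and 2 lower (856 unadjusted; no overlap for 11.5% of genes, 10% by chance). Cd274 (-0.88 ± 0.24, adjusted p = 0.459) and Braf (-1.11 ± 0.34, adjusted p = 0.549) did not pass. Rescaling to the same sum moved the median of all genes by -0.18 and called 2 higher and 1 lower. Without small RNA genes 0 genes passed, although the Pdcd1lg2 fold change was 5.11 as before (limma adjusted p = 0.0514). Fold changes correlated with GC content (Spearman 0.263 across genes) and with length (-0.124), and 1 gene passed with either trend removed. Pdcd1lg2 lost its call in both cases with its fold change nearly the same. It was 5.11 with the GC trend removed and 5.07 with the length trend removed (limma adjusted p = 0.101 and 0.108). The count was 2, 2 and 3 without control vehicle tumors 1, 2 and 3, and 3, 3 and 14 without control BRAFi tumors 1, 2 and 3. It was 3 without PD-L2 vehicle tumor 1, and 3 and 2 without PD-L2 BRAFi tumors 1 and 3.

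Gene lists under BRAFi ran the same way as under vehicle for interferon, hypoxia and glycolysis, with 0 members past the threshold over all genes in any list. Ribosomal proteins were higher in PD-L2 tumors (0.37, 29 of 29 members, camera adjusted p = 3.92e-17). Their median was 0.16 after rescaling to the same sum and 0.08 under quantile normalization. The same control BRAFi tumors gave the fall of this list against control vehicle tumors (-0.60), so this difference is not a separate result. Under vehicle the median was 0.12. Hypoxia genes were higher (0.64, 19 of 19 members, adjusted p = 2.15e-08; 3 adjusted over the list alone), with the vasodilator gene Adm at 2.74 ± 0.69. Glycolysis genes were higher (0.45, adjusted p = 8.72e-07; 5 adjusted over the list alone), with the lactate exporter Slc16a3 at 1.88 ± 0.42 and a median of 0.25 after rescaling to the same sum. Without control BRAFi tumor 1 the medians of these 2 lists were 0.33 and 0.27. The interferon list was lower (-0.94, 25 of 25 members, adjusted p = 6.27e-07), with Ifit1 at -1.28, but its call ended without control BRAFi tumor 1 (-0.24); it was -1.68 without control BRAFi tumor 2 and -0.56 without PD-L2 BRAFi tumor 3. Mitosis genes were lower (-0.24, 25 of 26 members, adjusted p = 6.27e-07; -0.44 after rescaling to the same sum), with the centromere protein Cenpa at -0.40 ± 0.14. Each of these 5 lists gave adjusted p = 0.806 with an estimated correlation, as did the 9 lists described next.

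These 9 lists passed with adjusted p from 0.00413 to 0.0414, and the call of each ended without at least 1 library. MHC class I presentation (-0.52) was -0.03 without control BRAFi tumor 1 and -0.17 without PD-L2 BRAFi tumor 3, which end the call, and -0.99 and -0.86 without control BRAFi tumor 2 and PD-L2 BRAFi tumor 1. Dendritic cell and MHC class II genes (-0.87) lost it without control BRAFi tumor 1 (-0.50) or 3 (-0.55) or PD-L2 BRAFi tumor 3 (-0.17), and were -1.59 without control BRAFi tumor 2 and -0.49 with no filter. Macrophage markers (-0.27) lost it without control vehicle tumor 1 or 3 (both -0.27), control BRAFi tumor 1 (-0.08) or 3 (-0.18) or PD-L2 BRAFi tumor 3 (0.07), and were -0.60 without control BRAFi tumor 2 or PD-L2 BRAFi tumor 2. Checkpoint genes (-0.27) lost it without control BRAFi tumor 1 (-0.08) or 3 (-0.31) or PD-L2 BRAFi tumor 3 (-0.17) and with a filter at a mean of 5 FPKM (-0.09). Chemokines and cytokines (-0.38) lost it without control BRAFi tumor 1 (-0.11) or 3 (-0.42) or PD-L2 BRAFi tumor 3 (-0.26), with -0.59 without PD-L2 BRAFi tumor 2. Cholesterol synthesis (-0.34) lost it without control BRAFi tumor 2 (-0.05) or PD-L2 BRAFi tumor 2 (-0.22). Unfolded protein response genes (-0.16) lost it without control BRAFi tumor 3 (-0.05), PD-L2 vehicle tumor 3 (-0.16) or PD-L2 BRAFi tumor 2 (-0.01) and with the replicate block (-0.16). Angiogenic factors (0.31) lost it without PD-L2 BRAFi tumor 2 (0.15), and were 0.55 without PD-L2 BRAFi tumor 3 and 0.14 after rescaling to the same sum. Extracellular matrix genes (0.19) lost it without control BRAFi tumor 2 (0.20) or 3 (0.15) or PD-L2 BRAFi tumor 2 (0.09) or 3 (0.18), under quantile normalization (0.16) and with the GC trend removed (0.13). They were 0.32 without PD-L2 BRAFi tumor 1 and -0.02 after rescaling to the same sum. That rescaling also ended the calls of 7 of these lists, MHC class I (-0.73), dendritic cell (-1.07), macrophage (-0.48), checkpoint (-0.47), chemokine (-0.57), cholesterol (-0.54) and unfolded protein (-0.36). These medians moved down along with the median of all genes, which rescaling moved by -0.18. The sum of PD-L2 BRAFi tumor 2 holds Mir2137 at 16.13%, and the part of that gene in the move was not tested.

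Averaged over both treatments, 12 genes differed between PD-L2 and control tumors, 8 higher and 4 lower (1642 unadjusted), all named here after their values were seen. Besides Pdcd1lg2, Mir212 and Mir1940, the higher genes were Fstl3, an activin antagonist (1.17 ± 0.13, adjusted p = 0.00847), the glutamate receptor Grik2 (1.18 ± 0.15), the transcription factors Sox4 (0.66 ± 0.09) and Jun (0.53 ± 0.08, adjusted p = 0.0333), and Pabpc4 (0.53 ± 0.07). The lower genes were Nkd2 (-1.43 ± 0.19, adjusted p = 0.0259), the phosphoinositide 3-kinase subunit Pik3r3 (-0.83 ± 0.12), Fam198b (-0.68 ± 0.10) and Dnajc3 (-0.57 ± 0.08). The count was 7, 4 and 5 without control vehicle tumors 1, 2 and 3, and 6, 4 and 33 without control BRAFi tumors 1, 2 and 3. It was 6 and 4 without PD-L2 vehicle tumors 2 and 3, and 7 and 23 without PD-L2 BRAFi tumors 1 and 2. Of the lists, 11 passed: interferon (-0.99), MHC class I (-0.60), dendritic cell and MHC class II (-1.17), macrophage (-0.45), checkpoint (-0.35) and mitosis genes (-0.09) were lower, and hypoxia (0.68), glycolysis (0.47), ribosomal protein (0.22), immediate early (0.35) and dedifferentiation genes (0.17) were higher. Their camera adjusted p ran from 4.46e-10 for ribosomal proteins to 0.0172 for mitosis; with an estimated correlation the smallest adjusted p was 0.674. Jun was the 1 immediate early member past the threshold over all genes, and 2 passed adjusted over the list alone. On that second count 12 glycolysis, 5 hypoxia and 5 ribosomal members rose, 2 checkpoint members fell, and 4 dedifferentiation members rose and 1 fell. The ribosomal call ended under quantile normalization (0.07) and the checkpoint call with a filter at a mean of 5 FPKM (-0.11). With no filter the dendritic cell and MHC class II median was -0.56. Rescaling to the same sum gave 0.09 for ribosomal, 0.22 for immediate early, 0.04 for dedifferentiation and -0.21 for mitosis genes. The macrophage median was -0.29 without PD-L2 vehicle tumor 3 and -0.30 without PD-L2 BRAFi tumor 3, where the dedifferentiation call ended (0.09). The mitosis call ended without control vehicle tumor 2 (-0.06), control BRAFi tumor 1 (-0.05) or 3 (-0.07), PD-L2 vehicle tumor 1 (-0.08) or 2 (-0.06) or PD-L2 BRAFi tumor 3 (-0.08), with -0.15 and -0.16 without control vehicle tumor 1 and control BRAFi tumor 2.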

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

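Of the tests in this part, only the removal of the length trend was chosen after the result was seen. Each result below is one in which the BRAFi response of PD-L2 tumors differed from that of control tumors by the interaction test, given as the PD-L2 response minus the control response on the log2 scale.

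Of single genes, Mir212 (limma estimate 4.18, adjusted p = 1.68e-05) and Mir1940 (3.61, adjusted p = 0.000107) passed, each above 0 in the 3 PD-L2 BRAFi tumors and listed at 0 in the other 9 libraries. Both are microRNA genes, whose FPKM is an unstable estimate, and with values listed at 0 the pseudocount of 1 sets the size of these estimates, so they are not fold changes. Of 100 splits run, 44 gave at least the 2 interaction calls of the real grouping, and the highest other split gave 2247. Those splits are not free of effects: reversing the treatment labels of the PD-L2 tumors turns the interaction into the sum of both BRAFi responses, which calls 2988 genes. The splits therefore cannot decide on chance, which stays not excluded.

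Of the lists, 7 passed with the preset correlation, all with adjusted p = 0.862 with an estimated correlation and with the smallest adjusted p of a protein-coding member at 0.956. Cholesterol synthesis genes differed by -0.59 (19 of 19 members lower, adjusted p = 5.07e-05), with the regulator Srebf2 at -0.59 ± 0.24; the call ended without PD-L2 vehicle tumor 3 (-0.35), and the median was -0.29 without control BRAFi tumor 2. Mitosis genes differed by -0.28 (26 of 26 lower, adjusted p = 1.28e-05), and by -0.16 without PD-L2 vehicle tumor 3. Ribosomal protein genes differed by 0.29 (29 of 29 higher, adjusted p = 3.36e-06), by 0.15 without control vehicle tumor 1, 0.19 without PD-L2 BRAFi tumor 1, 0.13 after rescaling to the same sum, 0.08 under quantile normalization and 0.18 with the length trend removed. Immediate early genes differed by -0.49 (adjusted p = 0.000626), with Fosb at -1.34 ± 0.37 and Egr3 at -1.40 ± 0.50; the call ended without PD-L2 BRAFi tumor 2 (-0.25), and the median was -0.75 without control BRAFi tumor 1. MAPK output differed by -0.28 (adjusted p = 0.0227), a call that ended without control vehicle tumor 1 or 2 (both -0.20), control BRAFi tumor 2 (-0.13) or 3 (-0.28), PD-L2 vehicle tumor 3 (-0.21) or PD-L2 BRAFi tumor 2 (-0.26) and after rescaling to the same sum (-0.42), with -0.47 and -0.43 without control vehicle tumor 3 and control BRAFi tumor 1. Oxidative phosphorylation differed by 0.13 (adjusted p = 0.00574), a call that ended without control vehicle tumor 1 (0.00) or control BRAFi tumor 3 (0.08), after rescaling to the same sum (-0.02) and with the length trend removed (0.00); it was 0.20 and 0.07 without control vehicle tumor 3 and PD-L2 BRAFi tumor 1. Endothelial markers differed by 0.50 (adjusted p = 0.0444), a call that ended without control vehicle tumor 1 (0.30), control BRAFi tumor 2 (0.40) or 3 (0.52), PD-L2 vehicle tumor 3 (0.38) or PD-L2 BRAFi tumor 2 (0.19) and under quantile normalization (0.54), with a filter at a mean of 5 FPKM (0.54), with a pseudocount of 0.1 (0.56) and shifted to the same median (0.51). The endothelial median was 0.76 without PD-L2 BRAFi tumor 3.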

How the results depend on the processing

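The tests that remove a length or GC trend, that leave out small RNA genes, and that combine the replicate block with the length correction were chosen after seeing the data; all others were planned. Of 660 gene results 98 passed and of 252 list results 76 passed, and no gene result reversed under any alternative. Mmp9 and Mir212 in PD-L2 tumors kept their calls under every alternative that tested them, and Mir1940 in all except the interaction with a pseudocount of 0.1. Of the 98 gene calls, 95 and 97 remained with pseudocounts of 0.1 and 0.5, 34 with no filter, 79 after rescaling to the same sum, 88 under quantile normalization, 15 of 96 in fits to 2 groups only and 22 of 91 with the length trend removed. Of the 76 list calls, 63 to 76 remained where camera with the preset correlation was run on other values of all 12 libraries or with 1 left out, and 42 of 46 in fits to 2 groups only. With fry 16 remained, and with a correlation estimated per list 0.

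Counts beyond 1.5 times the reported value were as follows, and the cause was not tested unless stated. For BRAFi in control tumors (899) they were 196 with no filter, 1436 after rescaling to the same sum, 2603 with arrayWeights, 18 with 2 groups only (fewer samples), 28 with the length trend removed and 27 with this and the replicate block. For BRAFi in PD-L2 tumors (29) they were 17 with no filter, 45 with a filter at 5 FPKM, 16 after rescaling, 46 under quantile normalization, 5144 with arrayWeights, 5 with 2 groups only, 11 with the GC trend removed and 3 with the block and the length correction. For PD-L2 under vehicle (0) they were 2 with either pseudocount, 7 with no filter, 2 with a filter at 5 FPKM, 1 under quantile normalization, 1584 with arrayWeights, 6 with 2 groups only, 1 with the GC trend removed and 2 without small RNA genes. For PD-L2 under BRAFi (9) they were 2 with no filter, 3 after rescaling, 1032 with arrayWeights, 2 with the replicate block, 3 with 2 groups only, 1 with the length trend removed, 1 with the GC trend removed, 0 without small RNA genes (856 unadjusted in the full set) and 1 with the block and the length correction. For the interaction (2) they were 1 with a pseudocount of 0.1, 0 with a filter at 5 FPKM, 27 with arrayWeights, 1 with the GC trend removed, 0 without small RNA genes, which both calls are, and 1 with the block and the length correction. For the BRAFi average (2988) they were 5397 with arrayWeights, 1480 with the length trend removed and 1158 with the block and the length correction, and for the PD-L2 average (12) 2785 with arrayWeights, 3 with the replicate block, 5 with the GC trend removed and 2 with the block and the length correction. The arrayWeights fit did not converge and gave PD-L2 BRAFi tumor 1 a weight of 15.69, so its counts say nothing of reliability, and lists were not run under it.

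Leaving out 1 library gave 0 (without control vehicle tumor 2) to 1649 (without control vehicle tumor 3) for BRAFi in control tumors, 3 (PD-L2 vehicle tumor 2) to 136 (control vehicle tumor 1) for BRAFi in PD-L2 tumors, 0 to 3 (PD-L2 vehicle tumor 1) for PD-L2 under vehicle, 2 to 14 (control BRAFi tumor 3) for PD-L2 under BRAFi, 2 to 5 for the interaction, 1355 (PD-L2 vehicle tumor 1) to 3337 (PD-L2 BRAFi tumor 2) for the BRAFi average and 4 to 33 (control BRAFi tumor 3) for the PD-L2 average. The direction of a list's test, which need not be that of its median, reversed in 5 cases: macrophage under BRAFi without PD-L2 BRAFi tumor 3 (0.07; -0.60 to 0.07 over the libraries left out), oxidative phosphorylation under vehicle without control vehicle tumor 1 (median -0.01, range -0.16 to -0.01), ribosomal proteins under vehicle with quantile normalization (-0.00) and without control vehicle tumor 3 (-0.05; range -0.05 to 0.22), and the interferon interaction, which had not passed, without control BRAFi tumor 2 (-0.56; range -0.56 to 0.80). The median alone changed sign in 3 other list calls. Cholesterol synthesis under vehicle did so without PD-L2 vehicle tumor 3 (0.33 to -0.02). After rescaling to the same sum extracellular matrix under BRAFi (0.19 to -0.02) and the oxidative phosphorylation interaction (0.13 to -0.02) did so. That rescaling moved the median of all genes by -0.18 and -0.14 in these comparisons. The extracellular matrix call stayed (camera adjusted p = 0.00318) and the oxidative phosphorylation call ended (0.0919). The correlation of the BRAFi responses (0.521) was 0.451 with a pseudocount of 0.1, 0.560 with a filter at 5 FPKM and 0.472 with the length trend removed. Replicate numbers showed no clear pairing of the tumors: of 12 correlations between same-numbered deviations, 3 exceeded 0.1 (range -0.37 to 0.24). Differently numbered tumors were not compared, so this cannot exclude pairing. The replicate block gave 1334, 29, 0, 2, 2, 3012 and 3 calls in the order of the comparisons above, with the BRAFi and PD-L2 averages last. Only PD-L2 under BRAFi (9 to 2) and the PD-L2 average (12 to 3) moved by over 1.5 times. The count for BRAFi in PD-L2 tumors stayed at 29, of which 15 were main calls. Depth is unknown, so its part in these limits cannot be given.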

Other observations

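The tests of the length trend as the whole cause of the calls, all tests of Braf and all tests of PD-L2 BRAFi tumor 2 were chosen only after the result was seen; the others were set before. Some tumors carried transcripts of other tissues. Acta1, the actin of skeletal muscle, was at 229 FPKM in control vehicle tumor 3, 96 in PD-L2 BRAFi tumor 3 and 49.9 in PD-L2 vehicle tumor 2, and at most 5.41 in the others. Krt14, a keratin of basal epidermis, was at 81.8 FPKM in PD-L2 BRAFi tumor 3 and at most 0.132 in the others. The simple-epithelium keratin Krt18 was at 91.4, 18.2 and 1.39 FPKM in control BRAFi tumors 1, 2 and 3, and the neural crest factor Sox10 at 24.9, 0.091 and 6.66 FPKM, so the treated control tumors differed among themselves in lineage genes.

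The numbers of calls were compared with other splits of the same libraries. For BRAFi in control tumors 1 of 10 splits, the real one, gave 899 calls and the highest other 3; for BRAFi in PD-L2 tumors 1 of 10 gave 29 and the highest other 2. For PD-L2 under vehicle 10 of 10 splits gave at least the real 0, with a highest other of 1. Any split reaches a count of 0, so this says nothing about chance. For PD-L2 under BRAFi 3 of 10 gave at least the real 9, and 1 split gave 32, several times the real count, which points to a structure of these samples; what it follows was not tested. Splits of 3 against 3 are too few for a share under 0.05. Over both backgrounds chance is excluded for BRAFi (2988 calls, 1 of 100 splits, highest other 13). For PD-L2 1 of 100 splits, the real one, gave 12 calls and the highest other 6. The 12 include the introduced gene Pdcd1lg2, and Mir212 and Mir1940, which were above 0 only in PD-L2 BRAFi tumors. The count was 3 with the replicate block and 4 to 33 with 1 library left out. No conclusion on the remaining genes is drawn from these splits, which also cannot tell PD-L2 from other differences between these tumors.

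BRAFi raised long transcripts and lowered short ones in both backgrounds, which may reflect RNA integrity or library preparation rather than the treatment. Across genes, each library's deviation from the mean correlated with length at -0.489 to 0.040 under vehicle and 0.166 to 0.429 under BRAFi. Ribosomal and mitochondrial genes alone do not carry it (Spearman 0.443 without them). With the fitted trend removed, 1178 of 2988 calls (39.4%) of the average effect still passed (median size 0.47 before and 0.30 after, median SE 0.112 and 0.094). The fitted trend is therefore not the whole cause of these calls. It rests on the longest annotated transcript and leaves GC content uncorrected, so a remaining part of a length or RNA quality effect is not excluded. In control tumors only, lists were set against 10000 random lists matched on length and level. MAPK output lay at percentile 100 (0.81 against -0.18 to 0.23) and ribosomal proteins at 0.08 (-0.60 against -0.50 to -0.18), both outside the random range. Oxidative phosphorylation lay at 2.87, within it (-0.42 to -0.12). The random genes were drawn independently within 10 bins of each measure, so the range leaves out that members of a list vary together. The test therefore cannot show that the ribosomal fall, which lies close to that range, exceeds what length gives. For the 899 calls in control tumors length and treatment cannot be told apart: 27 (3.0%) still passed, with 99.7% of signs kept, the median size falling from 0.70 to 0.47 and the median SE from 0.157 to 0.128.

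Braf itself was above the control vehicle mean in all BRAFi tumors, by 1.86, 2.77 and 1.17 in control and 0.82, 0.60 and 1.06 in PD-L2 tumors. In control BRAFi tumor 2, 5 of its 8 nearest tested genes were higher too: Mkrn1 (1.37), Dennd2a (1.40), Adck2 (1.41) and Ndufb2 (1.12) on one side and Mrps33 (1.64) on the other. Agk (-0.25), Ssbp1 (-0.04) and Clec5a (-0.49), beyond Mrps33, were not. The median of the 8 lay at percentile 99.82 of 11900 such windows there (median 1.25), which argues against a rise of Braf alone. In tumor 1 it lay at 76.47. Mkrn1 (0.89), Dennd2a (1.09) and Adck2 (0.69) were higher in that tumor, and a rise of Braf alone cannot be told apart from a regional one because the neighbours moved unevenly. In tumor 3 it lay at 27.06. A single form of window was run; the test was first set over both libraries jointly and was divided by library, with its prediction reworded, after the joint result was seen. The fitted length trend is excluded as the whole cause in tumors 1 and 2 only. Braf stayed 1.55 and 2.27 above the vehicle mean there with that trend removed. In tumor 3 it fell to 0.77 and in PD-L2 BRAFi tumors 1, 2 and 3 to 0.56, 0.24 and 0.60. The call of the control comparison ended, with 1.93 ± 0.34 before and 1.53 ± 0.29 after (limma adjusted p = 0.0288 and 0.0538). Both the fold and its error shrank. The adjusted p also depends on the other genes, and calls in that comparison fell from 899 to 28. A copy gain around Braf, a known route of resistance to BRAF inhibitors, is a candidate explanation for tumor 2 and possibly tumor 1, and stays a hypothesis, since DNA was not analysed here.

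PD-L2 BRAFi tumor 2 stood apart in genes chosen after their values were seen. The Y-linked genes Ddx3y, Kdm5d and Uty were at 3.6, 0.641 and 0.478 FPKM, 0.146, 0.136 and 0.11 of the mean of the other 2 tumors of its group. Pdcd1lg2, carried by the tumor cells, was at 20.8 FPKM, 0.119 of that mean. A larger share of cells from a female host cannot be told apart from other causes, because the values go both ways. Xist was at 2.98 FPKM, the highest of the group (1.94 and 2.61) but inside the 1.61 to 7.23 of the other libraries. Against the other 2 tumors, macrophage (0.90), dendritic cell (1.22), endothelial (0.94) and pericyte (1.13) lists were higher, as was the Schwann and neural crest list (0.13). Fibroblast (-0.02), neutrophil (-0.64), skeletal muscle (-1.58) and keratinocyte (-2.48) lists were not. The last 2 say little of host cells in tumor 2, because they are set against PD-L2 BRAFi tumor 3, which holds the Acta1 and Krt14 values given above. The bound of this test was reset after its result was seen. A control tumor under this label is excluded by Pdcd1lg2, which was 5.86 times the highest control library. Mir2137 took 16.13% of the summed FPKM, a share too small to lower other genes to the ratios of the Y-linked genes, so it is excluded as their cause. Such a share would lower every other gene alike, and the median ratio of the other tested genes to the group was 1.00 (quartiles 0.84 and 1.21). This test replaced one on rescaled values that could not have come out the other way. The bound set for the median ratio could not have been reached with that share either, so the size of the share decides. What lowered the Y-linked genes is not settled here.

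Il2rg, the cytokine receptor subunit disrupted in NSG mice and chosen after its values were seen, was at 5.85, 4.25 and 5.53 FPKM in control vehicle, 30.2, 24.1 and 13.1 in control BRAFi, 3.28, 3.59 and 2.88 in PD-L2 vehicle and 13.2, 3.57 and 17.1 in PD-L2 BRAFi tumors.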
